A study of Mus musculus with 72 samples.

How the data were processed

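Total RNA of CT26 tumors, spleens and tumor-draining lymph nodes of BALB/c mice was sequenced as paired-end stranded polyadenylated RNA libraries, per the labels. Per the submitters' processing notes, bcl2fastq 2.20 wrote the reads, STAR aligned them to mm10 and RSEM 1.3.0 gave the expression values; the annotation release is not stated. The authors deposited 1 table of log2(TPM + 1) values, rounded to 2 decimals, with a column per library and no pooling. The deposited log2 unit was checked on the values. The lowest steps are those of log2 of 1 plus multiples of 0.01, and no value lies under 0.01, so a value of 0.01 is a TPM of 0 or 0.01 and is called the floor here. TPM was scaled by the authors over all genes of their annotation, of which 16835 are listed, so the listed TPM of a library sum to less than the whole. The share left to unlisted genes was 13.5 to 17.8% in tumors, 40.4 to 59.1% in spleens, 14.1 to 23.8% in day 16 nodes and 17.1 to 22.2% in day 23 nodes. Globin genes and most class II genes are not among the listed genes and were not analysed here, which leaves 19 of the 21 panel genes. TPM keeps no read number, so the depth is unknown and the precision of a value comes from the spread between mice alone. Genes above the floor numbered 9765 to 10927 per tumor, 9918 to 11075 per spleen, 10956 to 12211 per day 16 node and 11301 to 12119 per day 23 node, and RNA integrity numbers ran from 4.5 to 9, with 1 library lacking one.

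The 72 libraries were matched to 24 groups of 3 by column name and label, with 0 columns unmatched. All nodes were sequenced in batch 2 and all spleens in batch 4, while tumors were 14 RNAlater samples of batch 3 and 4 fresh-frozen samples of batch 2. Positions were taken from GENCODE M21 for 16307 of the listed symbols that match an upper-cased mouse symbol. A check for duplicated libraries found 0 identical pairs, with a highest correlation of 0.996 over 12984 genes and 10378 genes differing in that pair, and 1 library was closer to another tissue than to its own. Whether libraries of 1 mouse pair across tissues was checked by correlating residuals within arms: the median r was -0.018 for spleen and node (18 mice), 0.039 for tumor and node (14 mice) and 0.037 for tumor and spleen (14 mice).

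Differential expression was tested in R 4.3.3 with limma 3.58.1 (linear model, trend and robust empirical Bayes) on the deposited values, keeping genes above the floor in at least 3 of the libraries fitted, with Benjamini-Hochberg adjustment at 5% within a comparison. Each tissue and day was fitted over its 18 libraries, with batch as a term in tumors. The PD1 effect is the mean of 3 differences (PD1 minus Isotype, PD1/CYTO minus CYTO, TS/PD1/CYTO minus TS/CYTO). The CYTO effect is the mean of CYTO minus Isotype and PD1/CYTO minus PD1, and the TS effect that of TS/CYTO minus CYTO and TS/PD1/CYTO minus PD1/CYTO. Arms were also compared with Isotype, the PD1 by CYTO and PD1 by TS interactions were tested, and day, day by treatment, tissue and log2 tumor volume were fitted as further terms. Fold changes on log2(TPM + 1) understate those of genes near the floor. For a list of genes, limma's camera was run with a preset correlation of 0.01 and again with an estimated correlation, and fry as a test of movement in 1 direction. In all 33 lists were fixed, and a list was tested where at least 5 of its genes were. The camera calls with the preset correlation numbered 2, 13 and 3 of 24 lists in tumors for PD1, CYTO and TS, 12, 8 and 13 of 29 in spleens, 14, 13 and 10 of 29 in day 16 nodes and 13, 14 and 15 of 29 in day 23 nodes. With an estimated correlation 1 of these held for TS at day 16 and 1 for CYTO at day 23, both the immature granulocyte list, and the report gives the estimated values. Tumor volumes, from the labels, were compared by exact permutation within matched arms, and list means were correlated with log2 volume with 1e+05 permutations; all tests are two-sided. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

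The groups, comparisons, tests, gene lists, panel and alternatives were written down before the data were examined. Genes are named by a rule: a panel of 21 genes in every tissue and day where measured; for PD1, CYTO and TS the 8 largest rises and 8 largest falls past 5% with the same sign in every pair of arms and a mean above the median of tested genes, or where none passed the 3 rises and 3 falls of smallest p; for an arm up to 3 rises and 3 falls; for day, tissue and tumor volume 8 and 8; and for a list up to 4 members of smallest p. Predicted genes and variable, diversity and joining segments of antigen receptors were left out. Some genes that the rule would name are not reported here. Genes outside the rule are said to be named after their values were seen.

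Alternatives were quantile normalization, no filter, a stricter filter keeping tested genes with a mean above the median of means, a pseudocount of 0.1 in place of 1, no batch term, leaving out the fresh-frozen tumors, RNA integrity, tumor volume or arm as a covariate, only the libraries of both groups, mouse as a replicate block, untransformed volumes, an estimated correlation and fry, and leaving out each library in turn. Rescaling the listed TPM of spleens, the pancreas list as a covariate, the nodes without 3 doubted libraries, quantile normalization for the lists, batch 3 alone, tumors against nodes within batch 2, RNA integrity as a covariate for day, day by factor and the node lists of arms and interactions, and the lists of day, day by factor and arms without the node that has no RNA integrity value were added after seeing the data. The procedure was tested on simulated data with the spread of each tissue and no correlation between genes: of 100 genes changed by 1 log2 unit for PD1 it recovered 85 in tumors, 91 in spleens, 80 in day 16 nodes and 97 in day 23 nodes, and for PD1 against Isotype 43, 69, 40 and 89, with 6 to 13 false calls. For PD1 the false calls were 10, 13, 11 and 11 among 194, 204, 181 and 208 called, above the 5% set in each. So were the 9 among 147 for PD1 against Isotype in tumors. Of 100 genes with a slope of 0.5 per doubling of volume it recovered 85, 100, 57 and 99, with 7, 12, 4 and 18 false calls among 191, 212, 144 and 217 called, above the 5% set in spleens and day 23 nodes. It called 0 genes where none was changed.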

Results

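RNA from tumors, spleens and tumor-draining lymph nodes (TDLN) was measured in BALB/c mice carrying CT26, a mouse colon carcinoma line, by stranded paired-end sequencing of polyadenylated RNA. The 72 libraries form 24 groups of 3 mice each, with every replicate of a group a separate animal. By their mouse numbers the day 23 nodes and spleens came from the same 18 mice, of which 14 also gave a tumor. Each of the 6 treatment arms was sampled in tumor, spleen and TDLN at study day 23 and in TDLN at day 16. PD1 and CYTO were each given alone and with each other, TS was given with CYTO or with both, and Isotype mice are the controls. CYTO and TS are used here as the labels write them, since the labels do not spell them out. Values are deposited as log2(TPM + 1) for 16835 genes under upper-case symbols, where TPM is transcripts per 1e+06. The lowest value, 0.01, is called the floor here and covers a TPM of 0 or 0.01. Read numbers are unknown, so no counting interval can be given. The listed genes held 821710 to 864649 TPM in tumors, 408819 to 596021 in spleens, 762240 to 858963 in day 16 nodes and 778070 to 829336 in day 23 nodes. Gene positions below are those of the mouse build GRCm38 (mm10).

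Tumor volumes of the sequenced mice were compared to describe how the arms differed in tumor size. At day 23 the 3 Isotype mice with a node library had tumors of 1002, 1623 and 1772 mm3 (mean 1466). The PD1/CYTO mice had 342 ± 339 mm3, the PD1 mice 954 ± 610 mm3 and the TS/PD1/CYTO mice 898 ± 1128 mm3 (SD, n = 3 each). Over the 3 matched pairs of arms, volume with PD1 was lower by a log2 difference of -1.48, with an exact two-sided permutation p = 0.02, which did not pass adjustment over the comparisons of that day (adjusted p = 0.16). PD1/CYTO against Isotype differed by -2.97 log2 with an exact permutation p = 0.1, the smallest that 3 against 3 mice allow. At day 16 the volumes ranged from 243 ± 55.2 mm3 in TS/PD1/CYTO to 379 ± 283 mm3 in PD1/CYTO (n = 3 each), and the PD1 difference was -0.09 log2 (exact permutation p = 0.799).

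Expression in day 23 tumors was related to tumor volume across the 18 tumors, to ask which transcripts went with tumor size. Genes of the interferon-gamma response and of T, NK and B cells were lower in larger tumors. Per doubling of volume, CXCL9, a chemokine that draws activated T cells (chromosome 5, 92321347 to 92328079), fell by 1.02 ± 0.20 (SE, log2, n = 18, adjusted p = 0.00321). CD74, the invariant chain of class II antigen presentation (chromosome 18, 60803848 to 60812652), fell by 1.14 ± 0.21 (adjusted p = 0.00263). IL18BP, an interferon-inducible inhibitor of interleukin 18, fell by 0.87 ± 0.14, and the guanylate-binding proteins GBP4 and GBP2 by 0.87 ± 0.19 and 0.81 ± 0.18. MPEG1, a macrophage pore-forming protein, FGL2 and the mast cell tryptase TPSAB1 fell by 0.82, 0.81 and 0.98. Of the 17 panel genes tested in tumors all 17 had negative slopes and 10 passed, among them the effector cytokine IFNG at -0.66 ± 0.12, CD8A at -0.64 ± 0.16, and the granule protease GZMB at -0.29 ± 0.07. The inhibitory receptors passed too, PDCD1 at -0.72 ± 0.17 and LAG3 at -0.57 ± 0.13, as did CD274 at -0.62 ± 0.12, ARG1 at -0.44 ± 0.13 and the complement gene C1QA at -0.49 ± 0.07. PRF1 (adjusted p = 0.103), JCHAIN (0.0521), COL1A1 (0.0619), MKI67 (0.433), S100A8 (0.222), CTLA4 (0.191) and IL2RA did not pass.

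Far fewer genes were higher in larger tumors. The scavenger receptor STAB1 (chromosome 14, 31139013 to 31168641) rose by 0.47 ± 0.13 log2 per doubling (adjusted p = 0.0223, n = 18) and the integrin ITGAV by 0.37 ± 0.12. DHX30, FUBP3, ATG9B, KNTC1, CFAP69 and FASTKD2 rose by 0.32 to 0.42. By limma with batch as a term, 1166 genes fell and 30 rose of 10913 tested, and the median slope over all genes was -0.12. With arm as a further term 450 genes passed, and quantile normalization gave 262 rising and 535 falling. Without the TS/PD1/CYTO tumors 60 or 59 the count was 484 or 642, and without PD1/CYTO 38, CYTO 12 or PD1 30 it was 4626, 2312 or 1872.

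All 20 measured genes of the interferon-gamma response list were lower in larger tumors, with a mean slope of -0.62, and 17 passed over all genes (19 adjusted over the list alone). CXCL10, CIITA, CXCL9 and GBP3 led the list, at -0.62 ± 0.10, -0.72 ± 0.13, -1.02 ± 0.20 and -0.74 ± 0.14. Of the 13 cytotoxic lymphocyte genes 10 fell (12 adjusted over the list alone), with IFNG, CCL5, CD8B and GZMA at -0.66, -0.64, -0.66 and -0.53. The 13 T cell genes had a mean slope of -0.46 and 10 fell (12 adjusted over the list alone), 6 of 7 NK cell genes fell (6 adjusted over the list alone), and 13 of 17 type I interferon response genes fell (15 adjusted over the list alone). Of 15 checkpoint and exhaustion genes 11 fell (12 adjusted over the list alone), including ENTPD1, CD244, HAVCR2 and CD274. As tests of a common direction, 21 of 24 lists passed with fry, which does not compare a list with other genes. With an estimated correlation between genes no list stood apart from the rest (adjusted p = 0.288 for the interferon-gamma and cytotoxic lists and 0.318 for T cells).

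Across the tumors, the cytotoxic lymphocyte mean had r = -0.78 with log2 volume (permutation p = 8e-05, adjusted p = 0.000624 over 24 lists) and Spearman rho = -0.80 (permutation p = 0.00013). The interferon-gamma mean had r = -0.72 (permutation p = 0.001, adjusted p = 0.0024) and rho = -0.81 (permutation p = 0.00012). The mean of the 5 B cell genes tested, of 11 listed, had r = -0.87 (permutation p = 1e-05, the smallest possible, adjusted p = 0.00024) and rho = -0.79 (permutation p = 0.00017). Without the 2 tumors farthest from the median volume r was -0.75, -0.69 and -0.82. In the 14 tumors of batch 3 r was -0.89, -0.75 and -0.89, and the 4 of batch 2 were too few for a value. With arm means subtracted r was -0.77, -0.76 and -0.87, and 18 of 24 lists passed in all.

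**Figure D1:**
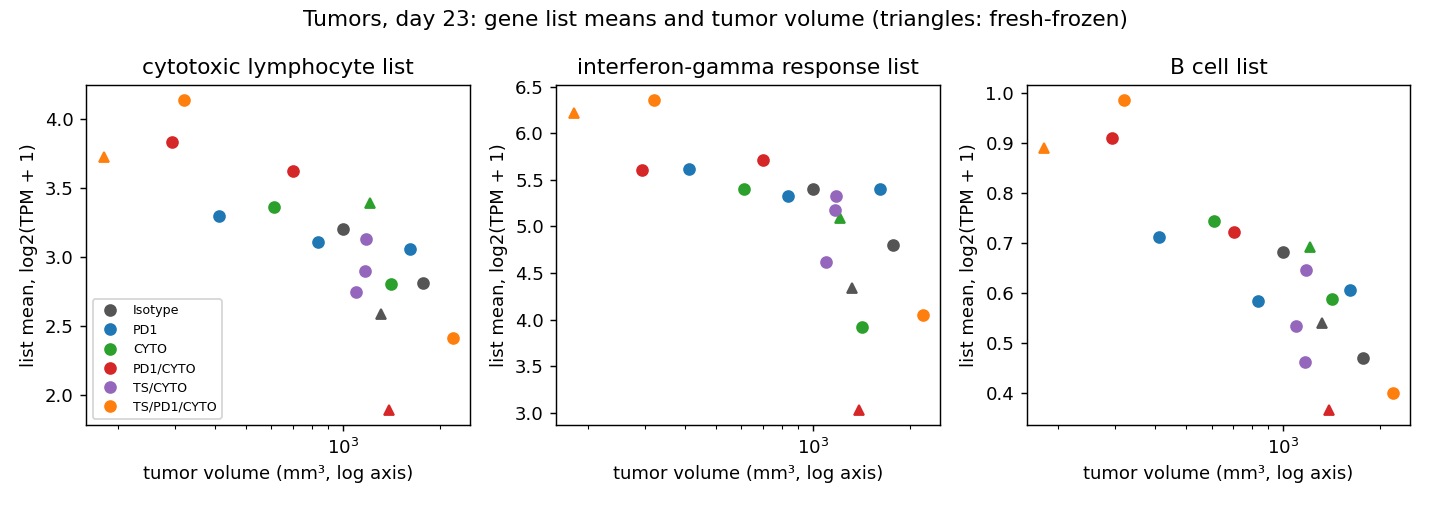
Mean log2(TPM + 1) of the cytotoxic lymphocyte, interferon-gamma response and B cell lists in each of 18 day 23 tumors, against tumor volume in mm3 on a log axis. Points are tumors, coloured by arm (circles RNAlater, triangles fresh-frozen). Pearson r with log2 volume, over tested genes (5 of 11 for B cells), was -0.78, -0.72 and -0.87.

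Treatment effects in tumors were estimated by comparing matched arms with and without PD1, CYTO or TS, to ask what each added component did at the tumor site. The macrophage list was higher with CYTO, where all 12 genes had positive differences and the mean was 0.41, led by APOE at 0.74 ± 0.31, VSIG4, MRC1 and CD163. Neither the list (adjusted p = 0.665 with an estimated correlation) nor any of its genes passed (0 of 12 over all genes). APOE, a lipid carrier of macrophages, had 8.18 ± 0.52 in Isotype and 9.52 ± 0.90 in PD1/CYTO tumors (SD, n = 3 each). With PD1 the interferon-gamma list had a mean difference of 0.36 with 18 of 20 genes higher, while with CYTO 18 of 20 were lower at a mean of -0.27 (adjusted p = 0.978 and 0.665 with an estimated correlation). CXCL9 stood at 5.31 ± 0.95 in Isotype, 5.73 ± 0.40 in PD1 and 5.39 ± 2.21 in PD1/CYTO tumors, and CD8A at 2.63 ± 0.71, 3.22 ± 0.23 and 2.43 ± 2.11. Of the 17 panel genes 16 were higher with PD1, none passing (PRF1 0.39 ± 0.15, IFNG 0.74 ± 0.36, GZMB 0.19 ± 0.18, smallest adjusted p = 0.666).

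No gene passed 5% by limma in tumors for PD1, CYTO or TS, for any arm against Isotype or for either interaction. The genes with the smallest p for PD1 were CHAC1 at 0.51 ± 0.15, RAB1B at 0.40 ± 0.12 and MTCH1 at 0.38 ± 0.12, and in the other direction the splicing kinase CLK1 at -0.53 ± 0.10, ORC4 at -0.36 ± 0.09 and EIF4A2 at -0.34 ± 0.10. For CYTO they were PF4 at 0.76 ± 0.30, IL1RN at 0.93 ± 0.37 and APOE at 0.74 ± 0.31, against ID1 at -0.59 ± 0.19, PLET1 at -0.85 ± 0.29 and KLF10 at -0.30 ± 0.13. For TS they were DHRS3, SPTAN1 and ARFGAP3 at 0.57, 0.93 and 0.57, against NPM3, GNG10 and CRIP1 at -0.40, -0.40 and -0.57. Unadjusted p under 0.05 was reached by 522 genes for PD1, 98 for CYTO and 369 for TS of 10913. PD1 against Isotype had 975 such genes and 0 past adjustment (smallest adjusted p = 0.0613), while a fit on the 6 tumors of those 2 groups alone called 706. Isotype 01 was the only batch 2 tumor in that fit, so the batch term took it up. The 706 calls thus rest on 3 PD1 against 2 Isotype tumors. The absence of calls rested partly on a single tumor. Without TS/PD1/CYTO 59 the counts were 71 for TS/PD1/CYTO against Isotype, 5 for PD1, 1 for TS and 4 for PD1 by TS.

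In the spleen, PD1/CYTO was set against Isotype to ask whether the combination reached a distant lymphoid organ. Most genes were higher in the PD1/CYTO spleens, with a median difference over all genes of 0.54 log2. ECE1, an endothelin-converting protease (chromosome 4, 137862237 to 137965229), was 2.61 ± 0.44 in Isotype and 4.48 ± 0.44 in PD1/CYTO spleens (SD, n = 3 each), a rise of 1.88 ± 0.51 (SE, adjusted p = 0.0469). WDFY4, needed for antigen cross-presentation (chromosome 14, 32959547 to 33185508), rose by 1.81 ± 0.57. The neutrophil protease CTSG (chromosome 14, 56099881 to 56102574) fell by 1.36 ± 0.46 (adjusted p = 0.0479), the histone gene H3F3C by 1.27 ± 0.42 and ACYP2 by 0.89 ± 0.28.

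By limma 2840 genes rose and 12 fell of 11184 tested. This call rested on single spleens and on the scale: without Isotype 08, Isotype 10, PD1/CYTO 38 or PD1/CYTO 39 it was 0, 1, 0 and 0 genes. After quantile normalization it was 1 (0 rising), after rescaling the listed TPM of every spleen to the same sum 1, with the pancreas list as a covariate 1, and with tumor volume or RNA integrity as a covariate 0. The median difference of all genes was 0.38 after rescaling and 0.03 after quantile normalization, so ECE1 and the other rises are to be read against that shift. RNA outside the listed genes took 52.6 ± 3.55% of TPM in Isotype and 43.3 ± 1.18% in PD1/CYTO spleens (SD, n = 3 each).

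IGHE, the constant region of immunoglobulin E (chromosome 12, 113269260 to 113273248), was 3.96 ± 0.61 in Isotype spleens, 0.44 ± 0.37 in TS/PD1/CYTO and 0.88 ± 0.83 in PD1 (SD, n = 3 each), and was at the floor in all 3 PD1/CYTO spleens. It was lower in the arms without PD1 too, at 0.91 ± 0.77 in CYTO and 1.85 ± 0.72 in TS/CYTO spleens. It was the 1 gene called for TS/PD1/CYTO against Isotype, where it fell by 3.52 ± 0.47 (SE, adjusted p = 0.0225), and it was singled out after its values were seen. In PD1/CYTO spleens its fall was larger at the same SE, so it was also among the 12 genes that fell there. The TS/PD1/CYTO call was lost without Isotype 08, Isotype 10, TS/PD1/CYTO 59 or TS/PD1/CYTO 60 (0 genes each), and under quantile normalization, a pseudocount of 0.1 or a stricter filter (0 genes). It was also lost with RNA integrity, tumor volume or the pancreas list as a covariate, after rescaling the listed TPM and in a fit on the 6 spleens alone (0 genes each). RNA integrity set these groups apart, with 6 to 7.5 in Isotype and 7.6 to 9 in TS/PD1/CYTO spleens. Immature granulocyte genes were lower with PD1 in the spleen, all 9 with a mean of -0.51, led by CTSG, MS4A3, MPO and CAMP, with adjusted p = 0.143 with an estimated correlation and 0 of 9 passing over all genes. With TS all 11 B cell and all 14 T cell genes were lower, at means of -0.55 (PAX5, CD79A, BANK1, CD22) and -0.50 (CD2, CD6, TRAC, CD5). Also with TS, 11 of 12 erythroid genes were higher at a mean of 0.18 (ALAS2, TFRC, EPOR, KLF1), and all 3 lists had adjusted p = 0.77 with an estimated correlation.

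No single gene passed by limma for PD1, CYTO or TS in the spleen, with 942, 2488 and 186 genes at an unadjusted p under 0.05. This rested on single spleens. Without TS/PD1/CYTO 58 the counts were 2779 for TS (2636 of them lower), 60 for CYTO (59 higher) and 3840 for PD1 by TS, without PD1/CYTO 40 it was 37 for CYTO (36 higher), and without PD1 28 or TS/CYTO 50 it was 1 for PD1. Those with the smallest p were KDM6A, FCHO2 and SWT1 at 0.39, 0.37 and 0.43 against the eosinophil granule gene PRG2 at -0.74 ± 0.23 and SLPI for PD1. For CYTO they were NUP214, SFPQ and TPR at 0.79, 0.64 and 0.84 against LSM1, C1D and TOMM20 at -0.35, -0.39 and -0.32. For TS they were EIF5, FAM220A and CAMTA1 at 0.29, 0.19 and 0.33 against PRG2 at -1.05 ± 0.28, ALKBH3 and HIST1H1C. Of the 17 panel genes tested, 16 were higher with CYTO (FOXP3 0.78 ± 0.36, LAG3 0.62 ± 0.34) and 16 were lower with TS (GZMB -0.62 ± 0.32, PRF1 -0.64 ± 0.40). S100A8 was at -0.54 ± 0.28 for CYTO and 0.01 ± 0.28 for TS, and none passed (smallest adjusted p = 0.219). The panel is to be read against the median difference of all genes, 0.25 for CYTO and -0.17 for TS.

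Spleen expression was also related to the volume of the tumor in the same mouse, to ask how the organ changed with tumor burden. Erythroid and dividing-cell genes were higher in spleens of mice with larger tumors, while most genes were lower, with a median slope over all genes of -0.09. Per doubling of volume, the red cell transcription factors GATA1 and KLF1 rose by 0.20 ± 0.05 and 0.19 ± 0.05 (SE, adjusted p = 0.0399, n = 18) and EPOR by 0.18, with 9 of 12 erythroid genes passing (11 adjusted over the list alone). TK1, TYMS, PCNA and BIRC5 rose by 0.21, 0.21, 0.16 and 0.22, within 13 of 15 proliferation genes (14 adjusted over the list alone). CXCL9 fell by 0.38 ± 0.07, UBD by 0.38 ± 0.09, and GBP4 and GBP2 by 0.31 each, within 17 of 18 interferon-gamma response genes (18 adjusted over the list alone). IGFBP3, the B cell chemokine receptor CCR6, S1PR1 and BCAR3 fell by 0.31 to 0.33. NACAD, BEX4, HMGB3, CENPW, CCNE2, SMIM1 and the neutrophil proteases PRTN3 and CTSG rose by 0.25 to 0.33. Of the 17 panel genes 14 passed, all lower in mice with larger tumors, with CD8A at -0.24 ± 0.08, FOXP3 at -0.28 ± 0.10 and JCHAIN at -0.20 ± 0.08, while S100A8 at 0.17 ± 0.08, MKI67 and COL1A1 did not.

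By limma 510 genes rose and 3932 fell with volume in the spleen. None passed with arm as a term or after rescaling the listed TPM (0 genes each), and 0 passed without any 1 of Isotype 08, Isotype 10, CYTO 18, PD1 29, PD1 30, PD1/CYTO 38, TS/PD1/CYTO 58 or TS/PD1/CYTO 59. Quantile normalization gave 1136 rising and 967 falling. Of 29 lists 17 passed with fry and 0 with an estimated correlation (adjusted p = 0.205 for the erythroid and proliferation lists). The share of TPM outside the listed genes had r = 0.65 with log2 volume (permutation p = 0.00238, adjusted p = 0.00397 over 5 measures), rho = 0.77 (permutation p = 4e-04), r = 0.57 without the 2 spleens farthest from the median and 0.64 within arms. With the erythroid mean that share had r = 0.77 (permutation p = 0.00025, adjusted p = 0.000625), rho = 0.79 (permutation p = 2e-04), 0.60 without those 2 and 0.87 within arms. The erythroid mean itself had r = 0.60 with log2 volume (permutation p = 0.00847, adjusted p = 0.0216 over 29 lists) and rho = 0.60 (permutation p = 0.00871), but r = 0.25 without the 2 farthest spleens, so that relation rests on them, and 0.74 with arm means subtracted. All spleens were of batch 4.

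**Figure D2:**
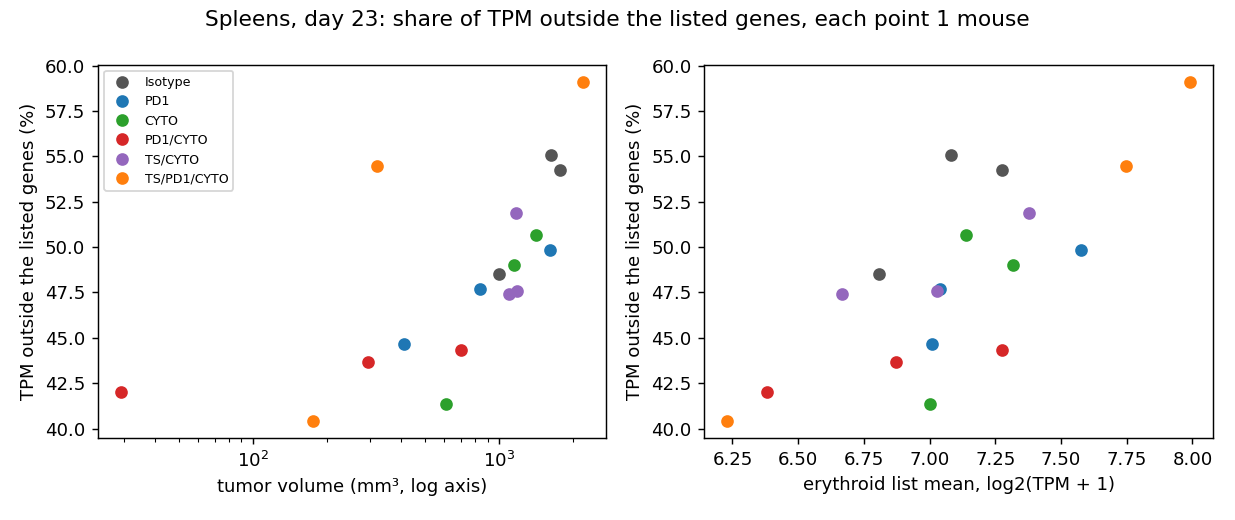
Percent of TPM outside the listed genes in each of 18 day 23 spleens, against tumor volume in mm3 on a log axis and against the mean log2(TPM + 1) of the erythroid list. Each point is a spleen, coloured by arm; the share had r = 0.65 with log2 volume and 0.77 with the erythroid mean.

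In day 23 nodes, arms with PD1 were set against matched arms without it, to ask what PD1 changed where tumor antigen drains. The chemokines CCL3 and CCL4, which recruit T and NK cells, were higher with PD1. CCL3 (chromosome 11, 83647844 to 83649355) was 0.58 ± 0.72 in Isotype, 1.51 ± 0.40 in PD1, 2.43 ± 0.26 in PD1/CYTO and 2.59 ± 0.71 in TS/PD1/CYTO nodes (SD, n = 3 each), and rose by 1.43 ± 0.21 over the 3 pairs of arms (SE, 9 against 9 nodes, adjusted p = 0.034). CCL4, beside it (chromosome 11, 83662584 to 83664683), rose by 1.15 ± 0.16 (adjusted p = 0.0313), from 1.50 ± 0.19 in Isotype to 2.05 ± 0.25 in PD1 and 2.92 ± 0.26 in PD1/CYTO. CXCL9 at 0.96 ± 0.17, IFNG at 0.72 ± 0.16 and C1QA at 0.44 ± 0.10 had adjusted p = 0.12 each and did not pass. IFNG was 0.61 ± 0.06 in Isotype, 0.61 ± 0.62 in PD1, 1.93 ± 0.16 in PD1/CYTO and 1.38 ± 0.05 in TS/PD1/CYTO nodes. CCL3 and CCL4 were the 2 genes past 5% by limma and were named after their values were seen. None was left without Isotype 08, Isotype 10, CYTO 19, PD1/CYTO 38, PD1/CYTO 39, TS/PD1/CYTO 59 or any 1 TS/CYTO node (0 genes each), while 15 rose and 72 fell without PD1 29. With tumor volume as a covariate 9 rose and 59 fell, after quantile normalization 8 rose and 24 fell, and under a stricter filter on expression 0 passed. In the first 3 of these settings most called genes were thus lower with PD1. The count was 4 without PD1 28, PD1 30 or TS/PD1/CYTO 60 (3 or 4 rising) and 1 with RNA integrity as a covariate.

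Granulocyte precursor genes stood out in the 3 PD1 nodes of day 23. MPO, the myeloperoxidase of granulocyte precursors (chromosome 11, 87793581 to 87804413), was at 6.93, 3.47 and 5.09 in these nodes and at the floor in all 3 Isotype, CYTO, PD1/CYTO and TS/PD1/CYTO nodes. ELANE (chromosome 10, 79886247 to 79888215) had 4.55 ± 1.76 in PD1 nodes (SD, n = 3) and was listed at the floor in every other arm at day 23. CAMP (chromosome 9, 109847379 to 109849617) had 6.14 ± 1.77 in PD1 against 0.58 ± 0.99 in Isotype nodes, CTSG 4.37 ± 1.61 against 0.04 ± 0.06, and MS4A3 3.39 ± 1.56 against the floor. S100A8, a calprotectin subunit of neutrophils (chromosome 3, 90668978 to 90670035), was 9.34 ± 1.67 in PD1 and 4.67 ± 1.22 in Isotype nodes. By limma 6 genes passed for PD1 against Isotype, all higher: MPO (adjusted p = 0.000799), CAMP, ELANE, CTSG (0.00118), MS4A3 (0.00696) and CD177 (0.0488), all named after their values were seen. All 8 tested genes of the immature granulocyte list were higher, 5 past 5% over all genes (6 adjusted over the list alone), with adjusted p = 0.00132 with an estimated correlation. The mature neutrophil list was higher too, with 6 of 7 genes, 0 over all genes (5 adjusted over the list alone) and adjusted p = 0.0262 with an estimated correlation. Without PD1 28 or PD1 30 the count was 3, without PD1 29 it was 23 (11 higher, 12 lower), and it was 0 under a stricter filter on expression and in a fit on the 6 nodes alone.

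**Figure D3:**
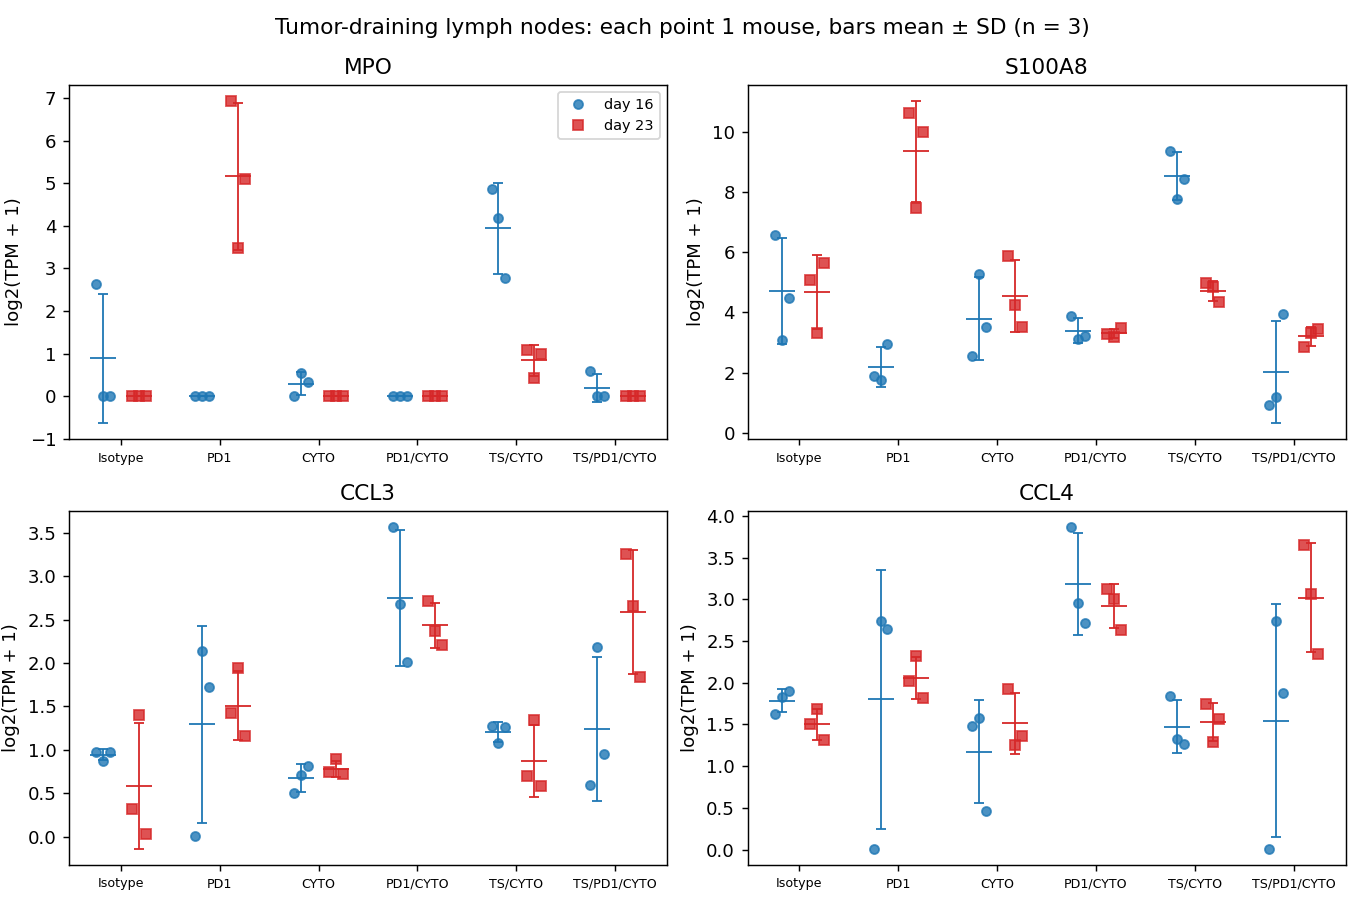
Log2(TPM + 1) of MPO, S100A8, CCL3 and CCL4 in each lymph node by arm, with blue circles for day 16, red squares for day 23 and bars for the mean ± SD of 3 mice. MPO reached 6.93 in a day 23 PD1 node and 4.86 in a day 16 TS/CYTO node, and CCL3 averaged 2.43 in day 23 PD1/CYTO and 0.58 in Isotype nodes.

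With CYTO these precursor genes were lower in day 23 nodes through the PD1 nodes, with MPO at the floor in PD1/CYTO nodes and at 3.47 to 6.93 in PD1 nodes. MPO and ELANE were at the floor in Isotype and CYTO nodes alike, so CYTO minus Isotype adds no fall for them. The immature granulocyte list fell by a mean of 2.56, with all 8 genes lower, 4 past 5% over all genes (8 adjusted over the list alone) and adjusted p = 0.00436 with an estimated correlation. CAMP (adjusted p = 0.0166), MPO (0.0207), CTSG (0.0394) and ELANE (0.0411) were called, and the PD1 by CYTO interaction of MPO passed (-5.15 ± 0.75 SE, adjusted p = 0.031). For MPO it is no separate result, since Isotype, CYTO and PD1/CYTO nodes were all at the floor, and its SE too was pooled over all 6 arms. The PD1 by CYTO interaction had 2 genes in all. It had 0 under a stricter filter, with RNA integrity or tumor volume as a covariate, and without any 1 Isotype, TS/CYTO or TS/PD1/CYTO node, CYTO 18, CYTO 19, PD1 30, PD1/CYTO 38 or PD1/CYTO 40. No gene was negative after quantile normalization or without CYTO 20 or PD1/CYTO 39, so MPO was lost there too, and 13 genes passed without PD1 29. TNFAIP3, a brake on NF-kappa-B signalling (chromosome 10, 19000910 to 19015657), rose by 0.40 ± 0.07 with CYTO (SE, 6 against 6 nodes, adjusted p = 0.0414), from 5.14 ± 0.11 in Isotype to 5.55 ± 0.02 in CYTO nodes (SD, n = 3 each). GPM6B (chromosome X, 166238911 to 166388988) rose by 0.36 ± 0.06 from 4.67 ± 0.01 to 5.10 ± 0.09. The short nucleolar RNA SNORA21, which this kind of library measures poorly, was at 2.75, 2.30 and 2.95 in PD1/CYTO nodes and at the floor in all other day 23 nodes but 1 CYTO node at 1.06, and RASSF6 differed by -0.64 ± 0.11.

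In all, 3 genes rose and 5 fell with CYTO by limma in day 23 nodes, the named ones other than TNFAIP3 and GPM6B being chosen after their values were seen. No gene fell with RNA integrity (2 rising) or tumor volume (1 rising) as a covariate, nor without any 1 CYTO node, PD1/CYTO 38 or PD1/CYTO 40 (1 rising each), so the calls of CAMP, MPO, CTSG and ELANE were lost there. The count was 0 under a stricter filter on expression, 4 after quantile normalization (1 rising) and 2 without any 1 Isotype node (1 rising). Without PD1 28, PD1 30, TS/CYTO 48 or TS/CYTO 50 it was 5, 5, 3 and 4. It was 14, 14 and 15 without PD1 29, PD1/CYTO 39 and TS/CYTO 49, with 5, 10 and 10 rising.

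Regulatory T cell, checkpoint and dendritic cell genes were slightly higher with CYTO in day 23 nodes, tested as lists that move on balance one way. All 10 regulatory T cell genes were higher at a mean of 0.33, with 0 over all genes (7 adjusted over the list alone), CTLA4 at 0.52 ± 0.14 and FOXP3 at 0.40 ± 0.13 (SE, 6 against 6), IKZF2 and TNFRSF18 among them. Of 15 checkpoint genes 14 were higher at a mean of 0.28, 0 over all genes (4 adjusted over the list alone), with HAVCR2, CTLA4, TNFRSF9 and CD274 first. Of 11 dendritic cell genes 10 were higher at a mean of 0.34, 0 over all genes (5 adjusted over the list alone), with ITGAE, FLT3, ZBTB46 and the cross-presenting cell marker XCR1 at 0.70 ± 0.20. All 9 MHC class I presentation genes (B2M, TAPBP, TAP1 and PSMB9 first) were higher at a mean of 0.20, 0 over all genes (3 adjusted over the list alone). The fry test gave adjusted p = 0.0427, 0.0427, 0.0427 and 0.0456 for these 4 lists, and the test against other genes gave adjusted p = 0.544, 0.544, 0.544 and 0.56 with an estimated correlation. These differences run with a median difference of all genes of 0.12 and with RNA integrity, which was 7.4 to 7.9 in Isotype and 4.7 to 7.2 in CYTO nodes. With RNA integrity as a covariate fry gave 0.0156, 0.00673, 0.0496 and 0.0621, and after quantile normalization 0.169, 0.275, 0.169 and 0.169, so none of the 4 is left on that scale. The adipocyte list was lower with CYTO by a mean of -1.38 in the same nodes (adjusted p = 0.216 with an estimated correlation).

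With TS the dendritic cell list was lower in day 23 nodes, with all 11 genes at a mean of -0.49, 0 over all genes (8 adjusted over the list alone). CCL17, a dendritic cell chemokine that draws CCR4-bearing T cells (chromosome 8, 94810453 to 94812036), was 2.43 ± 0.27 in CYTO and 0.91 ± 0.45 in TS/CYTO nodes (SD, n = 3 each), a difference of -1.37 ± 0.22 (SE, adjusted p = 0.0807), and CCL22, BATF3 and ITGAE followed. The fry test of the list gave adjusted p = 0.0182, and the test against other genes adjusted p = 0.369 with an estimated correlation. The adipocyte list was higher with TS by a mean of 1.85 in the same nodes (adjusted p = 0.369 with an estimated correlation, fry adjusted p = 0.217). SNORA21 was the 1 gene called for TS (-1.50 ± 0.16 SE), named after its values were seen, and the count was 0 under a pseudocount of 0.1 or under a stricter filter on expression.

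In TS/CYTO nodes of day 23 the type I interferon response rose against Isotype, with all 17 genes higher at a mean of 0.90 and adjusted p = 0.0151 with an estimated correlation, though 0 genes passed over all genes (16 adjusted over the list alone) and fry gave adjusted p = 0.0773. RNA integrity was 5.9 to 6.5 in these nodes and 7.4 to 7.9 in Isotype nodes. With it as a covariate all 17 stayed higher at a mean of 0.92, but the list no longer passed (adjusted p = 0.0779 with an estimated correlation). IFIT3, an interferon-induced antiviral gene (chromosome 19, 34583531 to 34588731), was 3.68 ± 0.23 in Isotype and 5.19 ± 0.84 in TS/CYTO nodes (SD, n = 3 each). MX1 was 3.51 ± 0.27 and 4.47 ± 0.55, IFIT1 2.38 ± 0.27 and 3.87 ± 0.86, and USP18 4.78 ± 0.20 and 5.53 ± 0.42. In TS/PD1/CYTO nodes macrophage genes were higher, all 11 at a mean of 0.74 (0 over all genes, 8 adjusted over the list alone), with C1QC beside the complement gene C1QA (chromosome 4, 136895917 to 136898803) at 0.95 ± 0.18 (SE) and C1QB. Their fry test gave adjusted p = 0.0128, with adjusted p = 0.0921 with an estimated correlation. All 11 B cell genes were lower there at a mean of -0.51 (0 over all genes, 11 adjusted over the list alone), with BLK at -0.76 ± 0.17, CD79B, PAX5 and CD22 first, fry adjusted p = 0.0587 and adjusted p = 0.365 with an estimated correlation. RNA integrity was 4.5 to 7.2 in these nodes. With it as a covariate the macrophage mean was 0.71 with 10 of 11 higher (fry adjusted p = 0.042, adjusted p = 0.0654 with an estimated correlation) and the B cell mean -0.43 with all 11 lower (0.328 and 0.445). The sodium channel gene SCN4A was the 1 gene called for TS/PD1/CYTO (-1.50 ± 0.21 SE, adjusted p = 0.0251), named after its value was seen, and no gene passed without Isotype 08, Isotype 10 or TS/PD1/CYTO 59 (0 genes each), while 25 rose and 13 fell without TS/PD1/CYTO 60.

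For the day 23 panel in nodes, 19 genes were tested and none passed for PD1, CYTO or TS, the smallest adjusted p being 0.0627 for S100A8 with CYTO (-3.08 ± 0.54 SE). GZMB stood at 0.58 ± 0.23, PRF1 at 0.25 ± 0.11, CD8A at 0.26 ± 0.17, IL2RA at 0.33 ± 0.14 and CD274 at 0.28 ± 0.10 for CYTO. LAG3 at 0.40 ± 0.13 and PDCD1 at 0.34 ± 0.12 were higher with PD1, with JCHAIN at 0.07 ± 0.41, ARG1 at -0.05 ± 0.26, MKI67 at -0.06 ± 0.20 and COL1A1 at -0.17 ± 0.23. No gene of the nodes passed for tumor volume by limma at day 23 (352 at an unadjusted p under 0.05).

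In day 16 nodes, the same comparisons asked what was in place at the earlier day. Granulocyte precursor genes were high in all 3 TS/CYTO nodes, where MPO was 4.86, 4.19 and 2.77 and S100A8 averaged 8.51 ± 0.80 (SD, n = 3), against 0.89 ± 1.52 and 4.71 ± 1.76 in Isotype nodes. The immature granulocyte list rose in TS/CYTO against Isotype by a mean of 2.32, with all 8 genes higher, CTSG, CAMP, MPO and MS4A3 first, 0 over all genes (5 adjusted over the list alone) and adjusted p = 5.4e-05 with an estimated correlation. The mature neutrophil list rose there by a mean of 1.41 with 6 of 7 genes higher, led by S100A9, S100A8, MMP8 and MMP9, 0 over all genes (3 adjusted over the list alone) and adjusted p = 0.000635 with an estimated correlation (fry adjusted p = 0.0628). Over both pairs of arms the immature granulocyte list rose with TS by 1.37 (adjusted p = 0.00956 with an estimated correlation). It was lower with PD1 by -1.39 with all 8 genes lower (fry adjusted p = 0.00973, adjusted p = 0.119 with an estimated correlation). For MPO this rests on the high TS/CYTO nodes, set against 0.58, 0.01 and 0.01 in TS/PD1/CYTO, and on Isotype 04 at 2.64. The PD1 arms also held the 3 nodes low in T and B cell genes described below.

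The type I interferon response fell in CYTO against Isotype nodes at day 16, with all 17 genes lower at a mean of -1.02 and adjusted p = 0.0333 with an estimated correlation, 0 over all genes (6 adjusted over the list alone) and fry adjusted p = 0.791. IFIT3 was 4.98 ± 0.48 in Isotype and 2.94 ± 0.19 in CYTO nodes (SD, n = 3 each), IFIT1 3.66 ± 0.39 and 2.30 ± 0.31, with MX2 and ISG15 also first. TS/CYTO nodes had IFIT3 at 3.70 ± 0.50, and the list fell there by a mean of 0.71 (adjusted p = 0.0352 with an estimated correlation, fry adjusted p = 0.988, 0 adjusted over the list alone). RNA integrity was 6.4 to 7.5 in CYTO and 7.9 to 8.3 in Isotype nodes. TS/PD1/CYTO 34 has no value for it, and without that node alone neither list passed (means of -1.02 and -0.71, adjusted p = 0.0626 and 0.0554 with an estimated correlation). With RNA integrity as a covariate, also without that node, the means were -0.64 and -0.64 (adjusted p = 0.175 and 0.0444).

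T and B cell genes set 3 day 16 nodes apart from the other 15. PD1 16, PD1/CYTO 22 and TS/PD1/CYTO 34 had T cell list means of 3.35, 2.39 and 2.84, where the others had 6.86 to 7.38. In the same nodes the B cell list means were 3.91, 1.18 and 2.85 against 7.11 to 8.01. Node 16 had the fat hormone ADIPOQ at 10.6, node 34 had ADIPOQ at 10.3 and the muscle creatine kinase CKM at 11.7, and node 22 had BAIAP2L1, an adaptor protein abundant in the tumors, at 9.34 and SPP1 at 11.7. Node 22 correlated across genes with the mean tumor at r = 0.975 and with the mean of the nodes at 0.806, genes not being independent replicates.

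**Figure D4:**
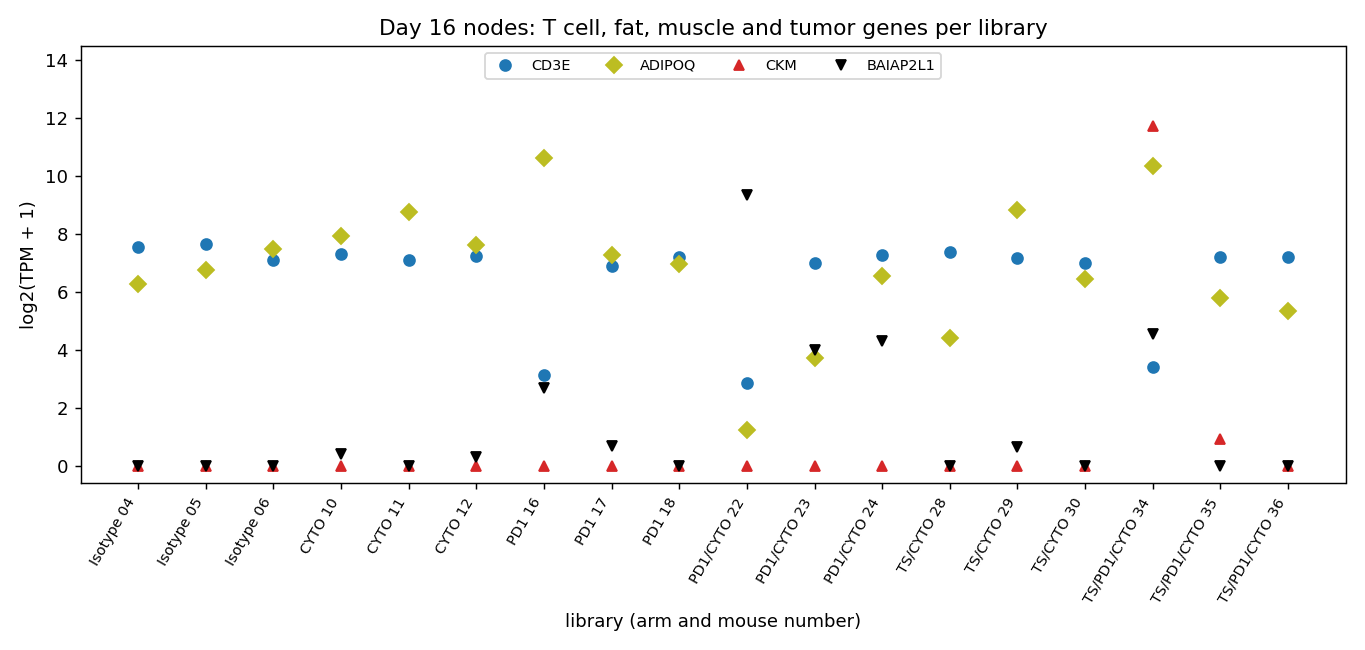
Log2(TPM + 1) of CD3E (T cells), ADIPOQ (fat), CKM (skeletal muscle) and BAIAP2L1 (abundant in the tumors) in each of the 18 day 16 nodes, named by arm and mouse number. CKM reached 11.7 in TS/PD1/CYTO 34, ADIPOQ 10.6 in PD1 16 and BAIAP2L1 9.34 in PD1/CYTO 22.

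With all 18 nodes no gene passed by limma at day 16 for PD1, CYTO or TS, with 905, 82 and 139 genes at an unadjusted p under 0.05, nor did any pass for an arm, an interaction or tumor volume. Without Isotype 04 the count was 4 for TS/CYTO against Isotype, and without PD1/CYTO 24 it was 13 for PD1/CYTO against Isotype. With all 18 nodes the smallest p belonged to RTP4 at 0.56 ± 0.16, ENTPD1 and FCER1G against S100A9 at -2.74 ± 0.47, GGACT and PACS2 for PD1. For CYTO they were FCER1G at 0.67, S100A4 at 1.56 and SPP1 at 2.66 against SYPL1, SLFN5 and GMPPB, and for TS DNAJB9 at 0.45, GMPPB and AHSA2 against ZFP36L2 at -0.63, CTC1 and EGR1 at -0.92. All 19 panel genes were tested and none passed (S100A8 -3.13 ± 0.54 SE for PD1, smallest adjusted p = 0.295), with CD8A at -1.50 ± 0.74 for PD1, moving with the 3 nodes just described.

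Without those 3 nodes, a choice made after seeing the data, genes abundant in the tumors were called in the remaining PD1/CYTO nodes. BAIAP2L1 was 3.99 and 4.30 in PD1/CYTO 23 and 24 and at the floor in all 3 Isotype nodes. FOSL1, an AP-1 subunit, rose there by 1.88 ± 0.16 (SE), IL1RL1 by 1.74 and STEAP1 by 1.44, making 4 genes with BAIAP2L1 (adjusted p = 1.51e-05) against 0 with all nodes. The other counts without the 3 nodes were 1 gene for PD1, 2 for CYTO and 4 for TS (HSPH1 and BANP higher, BAIAP2L1 and FOSL1 lower). For tumor volume 710 genes rose and 207 fell, with AREG, KRT19 and KRT8 rising by 2.18, 1.70 and 1.65 per doubling, the fat genes PCK1, RETN, ADIG, CFD and PLIN4 by 1.61 to 1.77, and the T cell genes CD28 and GPR174 falling by 0.30 and 0.34. As 6 genes high in every tumor and near the floor in spleens and most nodes, the tumor genes held 107% of the tumors' mean in node 22, 2.71% in node 24, 1.84% in node 23 and 1.55% in node 34. PD1 16 had 0.439% and the day 23 node PD1/CYTO 40 had 0.30%, while the highest of the other 30 nodes had 0.061%.

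Day 23 and day 16 nodes of the same arms were compared to ask how the nodes changed with time. By limma 0 of 12596 genes passed (2421 at an unadjusted p under 0.05, smallest adjusted p = 0.056), with the monocyte chemokine CCL8 at 0.72 ± 0.21 (SE), CFP and COLEC12 higher. The respiratory chain genes NDUFA10 at -0.34 ± 0.06 and SDHC at -0.36 ± 0.07 were lower, as was MED29. All 12 immediate early and heat shock genes were lower at day 23 by a mean of -0.38, with JUN, HSPA1A, HSPA1B and EGR1 first, 0 over all genes (3 adjusted over the list alone), fry adjusted p = 0.0416 and adjusted p = 0.313 with an estimated correlation. Without the 3 doubted nodes 12 genes rose and 279 fell, with CCL8 rising by 0.91 ± 0.18 (adjusted p = 0.0288) and NDUFA10 falling by 0.27 ± 0.05 (adjusted p = 0.0286). Without PD1/CYTO 23 of day 16 the count was 16. RNA integrity was lower at day 23, with a median of 6.65 against 7.7. Without TS/PD1/CYTO 34, which has no value for it, 0 genes passed and the immediate early and heat shock list had a mean of -0.35 (fry adjusted p = 0.06). With RNA integrity as a covariate on the same nodes 85 genes rose and 556 fell, and the list had a mean of -0.46 (fry adjusted p = 0.00857, adjusted p = 0.28 with an estimated correlation). The count for day therefore depends on how RNA integrity and the doubted nodes are treated.

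The effect of PD1 on granulocyte genes differed between the days. The difference of the PD1 effects, day 23 minus day 16, passed for 7 genes, all positive, with S100A8 at 3.77 ± 0.71 (SE, adjusted p = 0.0425), S100A9 (chromosome 3, 90692632 to 90695721) at 3.36 ± 0.66 (0.044). The other 5, named after their values were seen, were CAMP at 4.30 ± 0.65, MPO at 3.08 ± 0.48, CTSG at 2.40 ± 0.38, CD177 at 1.98 ± 0.38 and ELANE at 2.60 ± 0.51. The immature granulocyte list differed by a mean of 2.47, with 9 of 9 genes positive, 4 over all genes (9 adjusted over the list alone) and adjusted p = 0.000987 with an estimated correlation. The count was 3 without most single nodes, 10 without day 23 PD1 29, 2 after quantile normalization and 0 under a stricter filter on expression. Without the 3 doubted nodes 7 genes passed again, but not the same ones. CAMP at 4.30, PRTN3 at 3.63, MPO at 3.14, ELANE at 2.87 and CTSG at 2.39 were positive, and the tumor genes HMGA2 at -0.78 ± 0.11 and CFAP69 at -0.47 ± 0.08 negative. S100A8 and S100A9 did not pass there (adjusted p = 0.106 and 0.125), and CD177 was not called. Without TS/PD1/CYTO 34 alone 3 genes passed, and with RNA integrity as a covariate on the same nodes 4. S100A8 and S100A9 passed in neither (0.0575 and 0.0778 without that node, 0.107 and 0.144 with the covariate). The list kept a mean of 2.52 without those nodes and 2.53 with RNA integrity (adjusted p = 0.0177 and 0.00291 with an estimated correlation). No gene passed for the CYTO or TS effects between days (266 and 217 at an unadjusted p under 0.05). The immature granulocyte list differed for CYTO by a mean of -1.79 with all 9 genes negative, 0 over all genes (5 adjusted over the list alone) and adjusted p = 0.00243 with an estimated correlation. It kept -2.09 without the doubted nodes and -1.90 with RNA integrity (0.0108 and 0.0046).

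The tissues of day 23 were compared to describe what each held. Spleens had more red cell precursor transcripts than nodes, with the heme synthesis gene ALAS2 (chromosome X, 150547375 to 150570638) higher by 8.88 ± 0.26 log2 (SE, 18 against 18 libraries, adjusted p = 1.22e-34), BPGM by 4.03, TMCC2 by 5.14 and S100A8 and S100A9 by 4.38 and 4.37. All 12 erythroid genes rose at a mean of 6.20 (12 adjusted over the list alone, adjusted p = 0.000496 with an estimated correlation) and all 9 megakaryocyte and platelet genes at 3.23 (9 adjusted over the list alone, 0.00108). Nodes exceeded spleens in the high endothelial venule gene GLYCAM1 (chromosome 15, 103562759 to 103565081), which was lower in spleen by -12.39 ± 0.20, in CCL8 at -7.51, in the fat genes CFD at -6.83 ± 0.61 and FABP4 at -4.53, and in IGHG1 at -4.56. Tumors exceeded nodes in SPP1, or osteopontin (chromosome 5, 104435118 to 104441050), by 8.65 ± 0.24, ESM1 by 6.92, LGALS7 by 6.38, TIMP1 by 6.14, TNFRSF12A by 5.89 and IL1RL1 by 5.71. The same tumors were lower in IGHG1 at -11.73, IGKC at -11.14, JCHAIN at -10.05, CD79A at -9.07 and the T cell zone chemokine CCL19 at -8.98. Against spleens, tumors were higher in SPP1 most of all, CCL8, CCL2 and CCL7 by 7.71, 7.07 and 6.92, and LAMA5 by 6.79, and lower in IGKC at -10.61, ALAS2 at -9.43, CD24 at -9.29 and IGHM at -8.58.

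By limma 1161 genes were higher and 10169 lower in spleens than in nodes of 12761 tested, 3532 higher and 7388 lower in tumors than in nodes, and 6798 higher and 3157 lower in tumors than in spleens. The median differences over all genes were -0.92, -0.43 and 0.32. B cell genes were lower in tumors than in nodes by a mean of -7.06 (11 of 11 over all genes and over the list alone). T cell genes were lower by -5.22 (14 of 14 in both), each with adjusted p = 0.699 with an estimated correlation. Spleens (batch 4) shared no batch with another tissue, so tissue and batch cannot be told apart there. Of 18 tumors 14 were of batch 3, and 4, fresh-frozen, shared batch 2 with the nodes, which were in RNAlater. Within that batch 2597 genes were higher and 7730 lower in tumors than in nodes, and 10458 of the 10830 called genes tested there (96.6%) had the same direction. Batch alone thus does not account for that difference, though storage and tissue coincide in these 4.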

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

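The tests weighed in this part were all chosen after the results were seen; the comparison of the PD1 and CYTO effects between days was planned. The effect of PD1 in lymph nodes differed between day 23 and day 16 for granulocyte genes, by an interaction test. The difference, day 23 minus day 16 on the log2(TPM + 1) scale, was 4.30 for CAMP, 3.08 for MPO, 2.40 for CTSG, 2.60 for ELANE, 1.98 for CD177, 3.77 for S100A8 and 3.36 for S100A9, with adjusted p from 0.00459 to 0.044. The immature granulocyte list differed by a mean of 2.47 for PD1 (adjusted p = 0.000987 with an estimated correlation). For CYTO, the immature granulocyte list differed by a mean of -1.79 (adjusted p = 0.00243) and the mature neutrophil list by -1.0 (adjusted p = 0.0262, 6 of 8 genes lower, fry adjusted p = 0.293). Without the 3 doubted nodes S100A8, S100A9 and CD177 were not called and the tumor genes HMGA2 and CFAP69 were, at -0.78 and -0.47. The immature granulocyte list then kept 2.52 for PD1 and -2.09 for CYTO (adjusted p = 0.0177 and 0.0108), and with RNA integrity as a covariate 2.53 and -1.90 (0.00291 and 0.0046). That covariate leaves out TS/PD1/CYTO 34, which has no value for it; without that node alone they were 2.48 and -1.79 (0.000349 and 0.0104). The mature neutrophil list was lost for CYTO without the doubted nodes (0.243) and with the covariate (0.0684), and passed without that node alone (0.0465).

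The PD1 differences come mainly from 2 groups of nodes, since all 3 PD1 nodes of day 23 and all 3 TS/CYTO nodes of day 16 had MPO at 2.77 or above, and the highest of the other nodes was 2.64 in day 16 Isotype 04. The CYTO differences leave out the TS/CYTO nodes by definition. Of these groups only the PD1 nodes of day 23 enter them, as does day 16 Isotype 04. A rise throughout the body is not decided by the spleens of the same day 23 mice. There the immature granulocyte list had a mean of -0.53 for PD1 against Isotype, which did not pass (adjusted p = 0.134 with an estimated correlation). No blood was sequenced. Whether the day 23 rise needs the PD1 agent stays open. The day 16 TS/CYTO nodes lacked it (list mean 2.32 against Isotype) but are of another arm and day. Blood in the nodes stays open: the erythroid list of the PD1 nodes exceeded that of the other 15 day 23 nodes by 0.063 ± 0.222 (SE), but the platelet gene PPBP went with the granulocyte genes. PPBP was 2.96, 0.01 and 4.47 in the PD1 nodes and 2.46, 3.11 and 3.21 in the TS/CYTO nodes of day 16, and at the floor in 27 of the other 30 nodes. The platelet list was higher by 0.464 ± 0.371 (SE) in the PD1 nodes and by 0.371 ± 0.0967 in the TS/CYTO nodes than in the other 15 of their day. The globin genes that would help to decide it were not analysed here. The labels give both groups the mouse numbers 28, 29 and 30, and numbers 10, 12 and 18 also occur on both days, which is no test of a mix-up; a biological difference between the arms stays open and untested.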

How the results depend on the processing

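Alternatives added after the data were seen are the rescaled spleens, the pancreas covariate, the nodes without 3 doubted libraries, quantile normalization for the lists, batch 3 alone, tumors and nodes within batch 2, RNA integrity for day, day by factor and the node lists of arms and interactions, and the lists of day, day by factor and arms without TS/PD1/CYTO 34, which has no RNA integrity value; the others were planned. Among the largest rises and falls past 5% named by the rule, no gene reversed under an alternative. Other named genes were not followed, and with single libraries left out only S100A8 and S100A9 for day by PD1 were. In 21 gene counts of 7 results the balance of rising and falling genes turned. For PD1 in day 23 nodes 2 rose and 0 fell, but 8 and 24 after quantile normalization, 9 and 59 with volume as a covariate and 15 and 72 without PD1 29. For CYTO there 3 rose and 5 fell, but 2 and 0 with RNA integrity, 1 and 0 with volume, without any 1 CYTO node, PD1/CYTO 38 or PD1/CYTO 40, 10 and 4 without PD1/CYTO 39 and 10 and 5 without TS/CYTO 49. In those nodes the balance also turned for PD1 against Isotype without PD1 29 (11 and 12), PD1 by TS without TS/CYTO 49 (3 and 2) and TS/PD1/CYTO without TS/PD1/CYTO 58 (4 and 1) or 60 (25 and 13). In spleens it turned for volume after quantile normalization (1136 and 967), and for PD1/CYTO (0 and 1) after quantile normalization or rescaling, with the pancreas covariate and without Isotype 10. Also, 4 lists with the preset correlation passed in the other direction. For PD1 in spleens these were T cell (lower, then higher with RNA integrity as a covariate, adjusted p = 0.0164) and erythroid (lower, then higher without TS/PD1/CYTO 58, 0.0316). Without the 3 doubted day 16 nodes these were B cell for PD1 (lower, then higher, 0.000189) and adipocyte for TS (higher, then lower, 0.0397). With an estimated correlation none of them passed either way. The cause of a change was not tested except where the alternative leaves fewer genes or libraries. With mouse as a replicate block the tissue counts were 11368, 10781 and 10127 (spleen and node, tumor and node, tumor and spleen), close to those without it. List means related to tumor volume numbered 18 of 24 in tumors, and 20 after subtracting arm means, 21 after subtracting batch means, 18 after regressing out RNA integrity, 18 in batch 3 alone and 16 after quantile normalization, not all of them the same lists. limma-voom and the other count-based alternatives were not run, because the values are not counts. Unknown depth limits all statements on genes near the floor, MPO, ELANE, SNORA21 and IGHE among them.

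After quantile normalization the counts were 1 for CYTO, 1 for PD1 against Isotype, 2 for PD1 by CYTO and 797 for volume in tumors. They were 1 for PD1/CYTO, 0 for TS/PD1/CYTO and 2103 for volume in spleens, and 32 for PD1, 4 for CYTO, 2 for TS, 1 for CYTO against Isotype, 3 for TS/PD1/CYTO and 1 for PD1 by CYTO in day 23 nodes, with 1 for day and 2 for day by PD1. Lists past 5% were then 5 for PD1 and 5 for CYTO in spleens and 8 for PD1 in day 23 nodes. Without a filter PD1 against Isotype in tumors gave 2 and CYTO against Isotype in day 23 nodes 1. The stricter filter, which tests fewer genes, gave 487 for volume in tumors, 1197 for PD1/CYTO, 0 for TS/PD1/CYTO and 2177 for volume in spleens. It gave 2 for TS/PD1/CYTO and 0 for all other called comparisons in day 23 nodes (PD1, CYTO, TS, PD1 and PD1/CYTO against Isotype, both interactions) and for day by PD1, and 5873, 5537 and 5431 between tissues. A pseudocount of 0.1 gave 0 for TS/PD1/CYTO in spleens, 1 for TS/CYTO in day 16 nodes, and 0 for TS, 4 for PD1 by CYTO and 0 for PD1 by TS in day 23 nodes. Without the batch term tumors gave 1 for PD1 against Isotype and 700 for volume, and without the fresh-frozen tumors 6 lists for PD1. With arm as a covariate volume gave 450 in tumors and 0 in spleens.

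With RNA integrity as a covariate PD1/CYTO and TS/PD1/CYTO gave 0 in spleens, PD1/CYTO 4 in day 16 nodes, and in day 23 nodes PD1 gave 1, CYTO 2, and TS/PD1/CYTO and both interactions 0, with 6 lists for TS in spleens. With tumor volume as a covariate PD1/CYTO and TS/PD1/CYTO gave 0 in spleens, and in day 23 nodes PD1 gave 68, CYTO 1, TS/PD1/CYTO 50 and both interactions 0. On only the libraries of both groups PD1 gave 706 in tumors, where the batch term took up Isotype 01, and PD1/CYTO gave 1. In spleens so fitted PD1 gave 1, PD1/CYTO 6485, TS/CYTO 3155 and TS/PD1/CYTO 0. In nodes CYTO gave 12 and TS/CYTO 3 at day 16, and PD1 0, CYTO 158, PD1/CYTO 8 and TS/PD1/CYTO 0 at day 23. Rescaled spleens gave 1 for PD1/CYTO, 0 for TS/PD1/CYTO and 0 for volume, and the pancreas covariate 1, 0 and 2879. Without the 3 doubted nodes day 16 gave 1, 2 and 4 for PD1, CYTO and TS, 4 for PD1/CYTO, 2 and 3 for the PD1 by CYTO and PD1 by TS interactions, 917 for volume, 7 lists for CYTO and 5 lists for volume. The counts between days were then 291 for day, 2 for day by CYTO and 5 for day by TS, and 7 for day by PD1, with HMGA2, CFAP69 and PRTN3 in place of S100A8, S100A9 and CD177. With RNA integrity, and so without TS/PD1/CYTO 34, day gave 641 and day by PD1 4, against 0 and 3 without that node alone. Within batch 2 tumor and node gave 10327. With an estimated correlation 1 list passed for TS in day 16 nodes and 1 for CYTO in day 23 nodes, and 0 in the other 10 tests. Tests by fry gave 2, 0 and 1 for PD1, CYTO and TS in day 16 nodes, 1, 6 and 1 in day 23 nodes and 0 in tumors and spleens. On untransformed volumes the PD1 difference at day 23 was -493 mm3 (exact permutation p = 0.0828) and no longer passed unadjusted.

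Leaving out each library in turn, gene counts ranged as follows. Tumors: PD1 0 to 5, TS 0 to 1, PD1 against Isotype 0 to 1, TS/PD1/CYTO 0 to 71, PD1 by TS 0 to 4 and volume 484 to 4626. Spleens: PD1 0 to 1, CYTO 0 to 60, TS 0 to 2779 and PD1 by TS 0 to 3840 (both highest without TS/PD1/CYTO 58), CYTO against Isotype 0 to 1, PD1/CYTO 0 to 3540, TS/PD1/CYTO 0 to 4 and volume 0 to 7364. Day 16 nodes: PD1, CYTO, TS, CYTO against Isotype and PD1 by CYTO 0 to 1, PD1/CYTO 0 to 13, TS/CYTO 0 to 4 and PD1 by TS 0 to 2. Day 23 nodes: PD1 0 to 87, CYTO 1 to 15, TS 1 to 3, PD1 against Isotype 3 to 23, PD1/CYTO 1 to 2, TS/PD1/CYTO 0 to 38, PD1 by CYTO 0 to 13 and PD1 by TS 0 to 5. Day gave 0 to 16, day by PD1 3 to 10 and day by CYTO 0 to 6. Lists for PD1, CYTO and TS ranged over 0 to 6, 5 to 18 and 0 to 5 in tumors, 9 to 14, 6 to 10 and 6 to 15 in spleens, 11 to 15, 11 to 17 and 7 to 14 in day 16 nodes and 10 to 16, 7 to 16 and 12 to 18 in day 23 nodes.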

Other observations

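The tests of explanations and the counts over other splits in this part were chosen after the results were seen; the comparisons of arms with Isotype and the interactions were planned. In day 23 PD1/CYTO nodes, interferon genes stood above Isotype: 18 of 20 interferon-gamma response genes were higher at a mean of 0.47, 0 over all genes (11 adjusted over the list alone), with CXCL9 at 1.45 ± 0.29 (SE, n = 3 against 3), BATF2, GBP7 and GBP3 first. All 17 type I interferon response genes were higher there too, at a mean of 0.58, 0 over all genes (9 adjusted over the list alone). Each list had adjusted p = 0.238 with an estimated correlation. RNA integrity was 5.9 to 7.1 in these nodes and 7.4 to 7.9 in Isotype nodes, and with it as a covariate the means were 0.54 and 0.60 (adjusted p = 0.115 and 0.203). The type I list had a PD1 by TS interaction of -1.59 on average, with all 17 genes negative, 0 over all genes (17 adjusted over the list alone), fry adjusted p = 0.0124 and adjusted p = 0.101 with an estimated correlation. IFIT3 averaged 3.13 ± 0.43 in CYTO, 4.59 ± 0.41 in PD1/CYTO, 5.19 ± 0.84 in TS/CYTO and 3.68 ± 0.15 in TS/PD1/CYTO nodes (SD, n = 3 each). Macrophage genes had the opposite interaction, with all 11 positive at a mean of 1.01, 0 over all genes (9 adjusted over the list alone), fry adjusted p = 0.0124 and adjusted p = 0.109 with an estimated correlation. Germinal center genes were lower in CYTO than in Isotype nodes of day 23, with 9 of 10 negative at a mean of -0.66, 0 over all genes (7 adjusted over the list alone), RGS13, GCSAM and S1PR2 among the first and adjusted p = 0.411 with an estimated correlation. RNA integrity was 4.7 to 7.2 in the CYTO nodes, and with it as a covariate the mean was -0.40 with 8 of 10 negative (adjusted p = 0.467).

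Other tissue appeared in some samples. Exocrine pancreas genes took up to 0.995% of TPM in a spleen (median 0.00476%), with 3 spleens, Isotype 09, PD1 29 and TS/CYTO 48, at 0.849% or above. In spleens the list was lower with CYTO by a mean of -3.64 and with PD1 by -1.57, with adjusted p = 0.612 and 0.284 with an estimated correlation. In tumors all 8 skeletal muscle genes were higher with PD1 at a mean of 0.92 and had a PD1 by TS interaction of 2.51 (adjusted p = 0.978 and 0.624 with an estimated correlation). In day 16 PD1/CYTO nodes 8 of 11 suppressive myeloid genes were higher at a mean of 1.27, with SPP1, TREM2, PTGS2 and ARG1 first and adjusted p = 0.232 with an estimated correlation, in the nodes that also held the tumor genes.

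Most genes were higher in PD1/CYTO than in Isotype spleens, by a difference of library medians of 0.593 ± 0.124 log2 (SE). The share of RNA outside the listed genes alone would give 0.258, and after rescaling the listed TPM of every spleen to the same sum the difference was 0.376 ± 0.112, so that share cannot be the whole cause, although the gene count fell from 2852 to 1. Pancreas tissue taken along is argued against as the whole cause, since with the pancreas list mean as a covariate the difference was 0.586 ± 0.222. That covariate took the gene count from 2852 to 1 all the same: the median change over genes was 0.54 before and 0.54 after, but the median SE rose from 0.259 to 0.294, and ECE1 went from 1.88 ± 0.51 to 1.77 ± 0.58 (adjusted p = 0.111). More erythroid cells in spleens of mice with larger tumors may account for part of it: the erythroid list rose with the unlisted share within arms (r = 0.868), and library medians fell with it (r = -0.60). These correlations are within arms, while the shift lies between them. Between these arms the erythroid means overlapped, at 7.081, 6.808 and 7.276 in Isotype and 6.872, 7.275 and 6.383 in PD1/CYTO spleens. Globin transcripts were not analysed here, and a treatment effect apart from tumor size stays open, since PD1/CYTO mice also had the smallest tumors on average.

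T and B cell genes were far below the other nodes in 3 day 16 libraries, and each may hold other tissue. Skeletal muscle genes in TS/PD1/CYTO 34 exceeded the highest of the other 15 nodes by 9.83 log2 on average, and adipocyte genes in PD1 16 by 1.51, both as tissue taken along at dissection would. PD1/CYTO 22 correlated with the mean tumor at 0.975 and had an RNA integrity number of 8.2, which argues against low RNA quality in that node alone: PD1 16 had 5.1, the lowest of the day 16 nodes, and TS/PD1/CYTO 34 had no value. A swap with another library of this series would need a partner, and 0 tumor or spleen libraries resembled the nodes most. A wrong label with a sample from outside the series, tumor tissue taken with the node and tumor cells in the node stay open for PD1/CYTO 22.

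Other splits of the same libraries into groups of the same sizes were counted, 100 for each comparison with more than that many, the real one included. Where a split called many times more genes than the real one, a structure of the samples is possible but was not tested. For the 0 genes of the tumor effects all 100 splits gave as many, with at most 1729 genes for PD1, 3378 for CYTO, 2174 for TS and 1 for either interaction. In spleens they did so too, with at most 4801, 7277, 3696, 1560 and 4035 genes in another split, and in day 16 nodes with at most 534, 0, 1, 0 and 1, and 524 for tumor volume. Such counts came in a minority of the splits, since the median of the other splits was 0 genes in each case. No test separates a structure of the samples from genes that move with each other by chance. For tumor volume 2 of 100 gave as many in tumors (1196 genes, highest other 3594), 1 of 100 in spleens (4442, highest other 275) and all 100 in day 23 nodes (0 genes, highest other 2731). In tumors and spleens the share is under 0.05 only taken singly, without adjustment over the 4 volume tests. In tumors a split again called many more genes than the real one, so chance is not excluded there. In day 23 nodes 3 of 100 gave as many as the 2 genes of PD1 (highest other 1102), 2 as the 8 of CYTO (833), 7 as the 1 of TS (616), 4 as the 2 of the PD1 by CYTO interaction (410) and 8 as the 1 of PD1 by TS (845). Chance cannot be excluded for TS and PD1 by TS. For the others the share is under 0.05 only taken singly, without adjustment over these 5 comparisons. The highest splits again call many more genes than the real one, so chance is not excluded for them either. For day all 100 gave as many as 0 (highest other 0), as for day by CYTO (0) and day by TS (1). For day by PD1 and each tissue comparison the real split alone gave as many, with 7 genes against 0, and 11330, 10920 and 9955 against 0, 4745 and 5386 (spleen and node, tumor and node, tumor and spleen).

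For counts of lists with the preset correlation, chance cannot be excluded in any tissue. In tumors 85, 5 and 79 of 100 splits gave as many lists as PD1 (2, highest other 19), CYTO (13, highest other 18) and TS (3, highest other 17), and in spleens 30, 64 and 18 (12, 8 and 13, highest other 22, 22 and 21). In day 16 nodes 30, 36 and 54 did (14, 13 and 10, highest other 20, 21 and 21), and in day 23 nodes 43, 26 and 17 (13, 14 and 15, highest other 18, 19 and 19). An arm against Isotype allows 10 splits, too few for a share under 0.05. There the real and highest other counts were 2852 and 0 for PD1/CYTO in spleens, 1 and 0 for TS/PD1/CYTO in spleens, 6 and 0 for PD1, 1 and 1 for PD1/CYTO and 1 and 0 for TS/PD1/CYTO in day 23 nodes. For the remaining arms the real count was 0, with a highest other of 708 for PD1/CYTO, 1 for CYTO and 1 for TS/PD1/CYTO in tumors, 1 for CYTO in day 16 nodes and 0 in the rest.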
